A study of Homo sapiens with 6 samples.

How the data were processed

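RNA-seq read counts were analysed for 6 libraries of CAL27, an established human oral squamous cell carcinoma cell line. Per the labels, 3 libraries came from cells given an empty vector (control) and 3 from cells given a plasmid meant to overexpress TNFAIP2. Each library was placed in its group from its title, and the deposited columns were matched to libraries through the column names that the labels give. The labels do not say whether the 3 libraries of a group came from separate cultures, so p-values measure the spread between these libraries, which may be technical. The same labels give both groups the numbers 1 to 3 without saying that a number marks a shared culture or day.

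Per the labels' protocols, libraries were prepared with a stranded mRNA kit, which keeps track of the strand each transcript came from. The submitters' processing notes name Trim Galore 0.6.4, HISAT2 2.2.0, HTSeq 0.13.5 and the human builds GRCh38 and hg38. The strand setting used for counting and the annotation release are not given in the sources used here. The authors deposited whole-number counts of reads per gene, which were not normalized. The deposited table has 23384 gene identifiers, of which 18002 carry a symbol. It holds 0 entries without a gene identifier and 0 genes of the mitochondrial chromosome, and the lowest total over the 6 libraries is 1 count. Coordinates are those of the deposited table. Total counts were 3092261, 3527161 and 3247683 for control replicates 1 to 3 and 3497920, 3449191 and 3517878 for the overexpression-labelled replicates 1 to 3. Within each group, a chi-square test compared the counts of each pair of libraries over genes with at least 20 counts in the pair. The chi-square per degree of freedom ran from 5.07 to 19.4 and 0 pairs were identical, so every library was kept as a separate replicate.

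Exons of GENCODE release 29 were used to find deposited features whose exons lie opposite exons of a protein-coding gene (Python 3.11.15, pandas 2.3.3, pyranges 0.1.4 and SciPy 1.17.1). Of the deposited identifiers, 22828 had an exon model in that release. Of these, 22827 were on the same strand, 22828 on the same chromosome and 13098 had the same start and end. A feature was called opposite a gene when at least 50 exonic bases overlapped. Contained features were those with at least 90% of their exonic bases in such an overlap and a total of at least 60 counts. For each library, the own-strand ratio was taken as the median, over contained features, of the gene's count under its own name divided by the count of the opposite feature, with 0.5 added to both. The groups' ratios were compared with a two-sided exact permutation test.

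The comparison of overexpression-labelled against control libraries used edgeR 4.0.16 in R 4.3.3. Genes were filtered with filterByExpr by group, library sizes were scaled by TMM, and a robust quasi-likelihood fit was tested with glmQLFTest. P-values were adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. CPM values are counts scaled to library size in the usual CPM unit, with TMM factors. Log2 fold changes are overexpression-labelled minus control, and their standard errors (SE) were derived from the F statistic. Gene lists were compared with camera from limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, for lists with at least 5 tested members. Camera with an estimated correlation and fry were run beside it. The 35 lists, the design, the alternatives and the rule for named genes were fixed before the data were examined, and TNFAIP2 was kept out of every list. That rule took TNFAIP2, IKBKB, CHUK, IKBKG, RELA, NFKB1 and NFKBIA whatever their values, then the 10 largest rises and the 10 largest falls among genes past the threshold with a mean of at least 5 CPM, groups that do not overlap and a symbol that is not a clone, LOC or antisense name. It also took up to 4 members of each list past the threshold, and where fewer passed, members that did not pass could be given as values, highest mean CPM first. No gene passed, so the members named under their own names are among the most abundant of their lists. Values of some list members that the rule takes are not reported here.

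An added comparison was chosen after seeing the data. Counts of features opposite a protein-coding gene were summed by that gene, where the overlap was at least 50 bases and the feature's count divided by the overlapping bases was at least 5 times the gene's own count divided by all its exonic bases. Some pairs of protein-coding genes met this limit in both directions. These sums were fitted in the same way, and the lists were tested on them by the name of the opposite gene. Genes named from that comparison were chosen after their values were seen. Alternatives covered DESeq2 1.42.0 and limma-voom, other scalings, other filters, a replicate block and leaving out each library in turn. Added after seeing the data were the own-strand ratio (as log2) as a covariate, the genes without an opposite-strand overlap alone, and other limits on the overlap and on the ratio of reads per base.

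The fit was tested on simulated data with 200 changed genes. Under their own names, for 11851 genes, 21% of genes changed 2-fold and 62% of genes changed 4-fold were recovered, and 5.68% of calls were false. For the 3134 sums of opposite-strand features, the shares were 68% and 92%, with 6.98% of calls false. Genes were simulated independently, without differences between libraries shared by many genes, so these shares may not hold for the real libraries.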

Results

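RNA-seq counts were examined for 6 libraries of CAL27, a human oral squamous cell carcinoma line, in which 3 vector control libraries were compared with 3 libraries labelled TNFAIP2 overexpression. TNFAIP2 is a gene induced by tumour necrosis factor. By the title of the series, the question was whether TNFAIP2 acts on NF-κB signalling through the kinase IKKβ, the product of IKBKB, in the spread of this cancer to lymph nodes. The libraries held between 3092261 and 3527161 counts each.

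Counts under TNFAIP2's own name were not higher in the libraries labelled TNFAIP2 overexpression. The gene (ENSG00000185215, chromosome 14, 103121476 to 103137439, plus strand, GRCh38) had 194, 112 and 162 counts in control replicates 1 to 3 and 194, 152 and 142 counts in the overexpression-labelled replicates 1 to 3. In TMM-scaled units this was 51.3 ± 17.3 CPM in controls and 44.3 ± 6.46 CPM in overexpression-labelled libraries (SD, n = 3), a log2 fold change of -0.21 (SE 0.28, edgeR adjusted p = 0.881). The sign was not stable, since the log2 fold change was 0.074 without control replicate 1. Counts under a gene's own name may also be a small share of its reads, as described below. Those of TNFAIP2 may thus not measure its transcript. They therefore give no check of the group labels or of the overexpression, and both groups are named here only as labelled. LINC00677 on the other strand spans the start of TNFAIP2, but no overlap of exons was found for it. It had between 0 and 2 counts per library, which does not show how many TNFAIP2 reads lay on that strand.

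Most counts in the table lay on features opposite abundant genes and not on those genes. The highest mean count, 157570 per library or 4.65% of all counts, was that of BEST1 on the plus strand of chromosome 11, whose exons overlap 1267 exonic bases of the ferritin heavy chain gene FTH1 on the other strand. FTH1 under its own name had a mean of 4833 counts. A lncRNA inside the glycolytic gene GAPDH (ENSG00000269968, chromosome 12, 6537794 to 6538370, minus strand) had 57218 counts and GAPDH had 4586. KRT8 had 19801 counts and overlaps 525 exonic bases of KRT18, which had 1032. C10orf55, opposite the urokinase gene PLAU, had 11049 counts and PLAU had 536. Of the 30 features with the highest mean counts, 27 lay opposite a protein-coding gene, and 5733 such features held 68.3% of all counts.

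**Figure D1:**
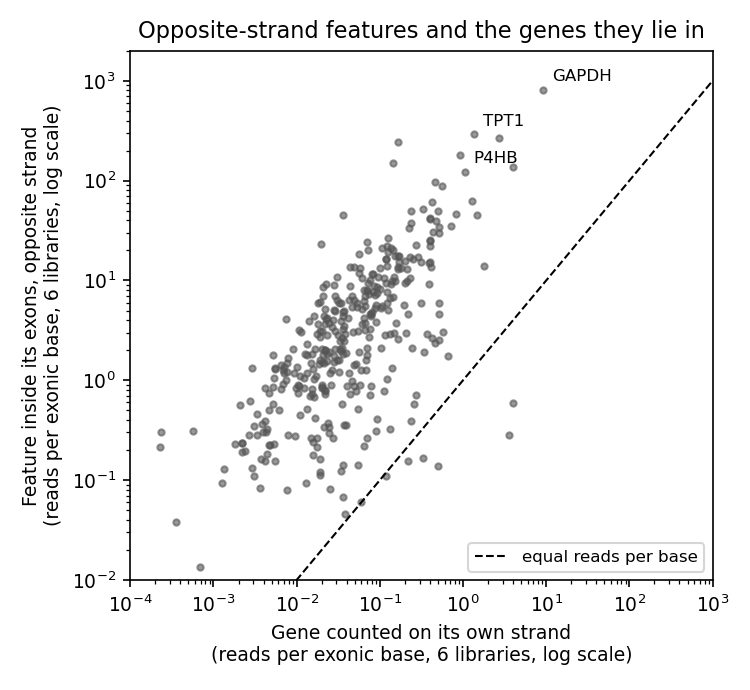
Each of the 364 points is a feature whose exons lie almost wholly inside the exons of a protein-coding gene on the opposite strand. The horizontal axis gives the gene's reads per exonic base under its own name and the vertical axis those of the feature, both summed over the 6 libraries and on log scales. Nearly all points lie above the dashed line of equal reads per base, GAPDH among them.

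Of 369 such contained features, 363 held more reads per base than the gene they lie in, with a median ratio of 76.4 (5 of the genes had no counts and are not drawn in the plot of contained features). At these genes, the counts under the gene's own name were thus few beside those of the feature. TNFAIP2 is not among them, and with no feature found opposite its exons, what share of its reads its own counts hold could not be measured. The own-strand ratio, the median of the gene's own count over that of the opposite feature, was 0.102, 0.0991 and 0.180 in control replicates 1 to 3 and 0.198, 0.134 and 0.192 in overexpression-labelled replicates 1 to 3. The means were 0.127 ± 0.0459 and 0.175 ± 0.0353 (SD, n = 3), a difference that did not pass an exact two-sided permutation test (p = 0.2, where 0.1 is the smallest this design can give).

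**Figure D2:**
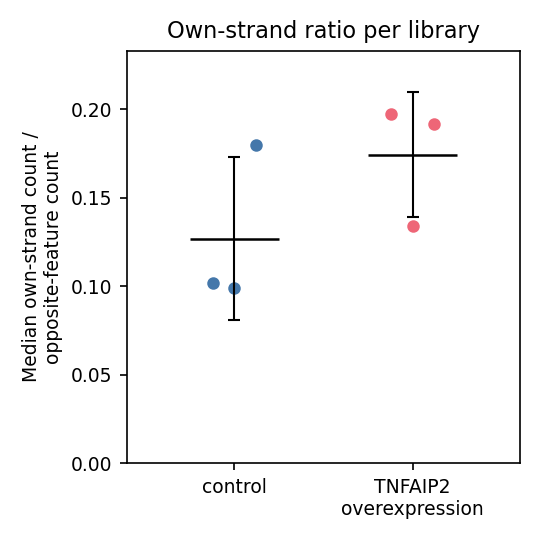
The own-strand ratio (vertical axis, no unit) is drawn for each library (points) of the control and TNFAIP2 overexpression groups, with the group mean (line) and SD (bars, n = 3). Control replicate 3, at 0.180, lies with the overexpression-labelled libraries and above control replicates 1 and 2.

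Under the genes' own names, no gene passed the test between the groups. Of 11851 genes tested with edgeR, 0 passed an adjusted p of 0.05. An unadjusted p below 0.05 was found for 580, of which 217 were higher and 363 lower in the overexpression-labelled libraries. A share of about 0.05 of the tested genes would fall below that limit if no gene differed, so this count is no sign of a difference. The lowest adjusted p was 0.0778, for PRAL, a feature opposite the interferon-stimulated gene XAF1, with a log2 fold change of -1.70 (SE 0.29). Next were the lncRNAs ENSG00000257452 and ENSG00000228318, opposite the interferon-stimulated antiviral genes OAS1 and MX1, with log2 fold changes of -1.13 (SE 0.22) and -0.98 (SE 0.19) and adjusted p = 0.184 for both. These features were named after their values were seen. DESeq2 called 3 features, these same ones, all lower, with adjusted p = 0.000821 for the feature opposite XAF1 and 0.00344 for those opposite OAS1 and MX1. Limma-voom called 1 feature, PRAL. Without control replicate 3, the library with the highest own-strand ratio of the controls, edgeR called 922 genes, 514 of them higher, and without control replicate 1 or overexpression-labelled replicate 2 it called 1, PRAL.

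Genes of the IKK complex and of NF-κB did not pass the edgeR test. IKBKB had 2.92 ± 2.81 CPM in controls and 4.52 ± 0.618 CPM in overexpression-labelled libraries, a log2 fold change of 0.61 (SE 0.77, adjusted p = 0.874). The value rested on single libraries, at 0.323 CPM in control replicate 2, and was 0.11 without it, 1.66 without control replicate 3 and 0.026 with the own-strand ratio as a covariate. The other kinase subunit gene CHUK had a log2 fold change of 0.51 (SE 0.46). The regulatory subunit gene IKBKG lay the other way at -0.37 (SE 0.20, unadjusted p = 0.0760, adjusted p = 0.830, and 0.0674 without control replicate 3), and its reads cannot be assigned to it alone. The transcription factor genes RELA and NFKB1 had log2 fold changes of 0.14 (SE 0.26) and 0.02 (SE 0.31), and the inhibitor gene NFKBIA one of -0.01 (SE 0.25). The sign of the NFKB1 and NFKBIA values turned under several alternatives.

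Genes that NF-κB induces were not called as a group under their own names. Of 26 tested NF-κB target genes, 18 had a positive log2 fold change and 0 passed the threshold (camera adjusted p = 0.368). Among the most abundant members, the chemokine gene CCL2 had 89.4 ± 9.38 CPM in controls and 98.4 ± 19.5 in overexpression-labelled libraries. TNIP1 had 146 ± 11.2 and 158 ± 27.1 CPM, and IER3 86.7 ± 26.6 and 100.2 ± 27.8 CPM. SOD2, at 487 ± 29.6 and 391 ± 6.57 CPM, lies opposite WTAP, and its reads cannot be told from those of that gene. Of 23 IKK and NF-κB signalling components, 17 had a positive value (adjusted p = 0.141), and of 14 cytokine and chemokine genes 10 did (adjusted p = 0.187). CXCL1 had 34.1 ± 5.61 and 44.0 ± 3.34 CPM, and IL1A 33.3 ± 11.5 and 41.8 ± 4.54 CPM.

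Camera placed 6 of the 29 tested lists higher in the overexpression-labelled libraries, with 0 members past the threshold over all genes and 0 when adjusted over the list alone. Cytosolic ribosomal proteins had 55 of 57 positive log2 fold changes (median 0.27, adjusted p = 3.85e-05), with RPS2 at 1169 ± 118 CPM in controls and 1424 ± 128 CPM in overexpression-labelled libraries. G2/M and mitosis genes had 28 of 34 (median 0.41, adjusted p = 0.000142), with the proliferation marker MKI67 at 102 ± 5.00 and 124 ± 8.22 CPM and the mitotic kinase PLK1, which lies opposite ERN2, at 74.2 ± 29.8 and 107 ± 22.0 CPM. Mesenchymal transition markers had 13 of 13 (median 0.46, adjusted p = 0.00583), with TNC, which encodes tenascin C and lies opposite DELEC1, at 168 ± 48.2 and 223 ± 42.0 CPM. Nuclear-encoded oxidative phosphorylation genes had 26 of 31 (adjusted p = 0.00803), ribosome biogenesis and MYC-responsive genes 23 of 30 (adjusted p = 0.00958) and proteasome subunits 24 of 31 (adjusted p = 0.0499). With an estimated correlation, 0 of the 29 lists passed, and the unadjusted p of these 6 were 0.0992, 0.157, 0.190, 0.105, 0.193 and 0.433 in the order given. Fry called 0 lists, in either its directional or its mixed form. The mean own-strand ratio was 0.127 in controls and 0.175 in overexpression-labelled libraries, and with it as a covariate 1 of the 6, the ribosomal proteins, was still past the camera threshold (p = 0.110 with an estimated correlation under the same covariate). Without control replicate 1 or overexpression-labelled replicate 3, camera called 2 lists, and 10 without control replicate 3. Without control replicate 2 or overexpression-labelled replicate 1 it called 3.

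Among the other 23 tested lists, adjusted p ran from 0.0676 to 0.998 by camera. The median log2 fold change of all tested genes was 0.02. Protein-coding genes held 50.3, 50.2 and 56.0% of counts in control replicates 1 to 3. In overexpression-labelled replicates 1 to 3 they held 57.6, 53.4 and 56.4%. The share of positive values among all protein-coding genes was not computed, so the counts of positive values by list lack that baseline. Hypoxia and glycolysis genes had 29 of 37 positive log2 fold changes, integrins, laminins and adhesion genes 19 of 24, NRF2 targets 16 of 21, G1/S and DNA replication genes 31 of 40, cholesterol synthesis genes 22 of 28 and angiogenesis and lymphangiogenesis ligands 15 of 17. VEGFA, the main angiogenic ligand, had 83.5 ± 7.45 CPM in controls and 91.7 ± 11.1 CPM in overexpression-labelled libraries. For invasion-related genes, 12 of 15 metalloproteinase and plasminogen genes were positive (adjusted p = 0.187), with MMP14 at 82.0 ± 7.07 and 97.5 ± 11.8 CPM. Positive values were found for 17 of 23 YAP/TEAD targets, 15 of 20 basal and stress keratinocyte genes, 19 of 28 unfolded protein response and ATF4 targets, 17 of 26 immediate early and AP-1 genes and 12 of 17 TGF-β targets. They were also found for 15 of 20 epithelial markers, 12 of 19 cytosolic heat shock genes, 13 of 20 apoptosis regulators, 13 of 20 p53 targets, 6 of 11 squamous differentiation genes and 7 of 11 exocyst and Ral genes. For squamous differentiation genes the median log2 fold change was 0.06 and camera's direction was down. Antigen presentation genes were evenly divided, with 11 of 22 positive. Interferon-stimulated genes went the other way, with 6 of 28 positive (median -0.13, adjusted p = 0.141). Replication-dependent histones, mitochondrially encoded genes and markers of fibroblasts, endothelium, leukocytes, and melanocytes or neural cells had 2, 0, 0, 1, 4 and 3 tested members, too few for a test.

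Features opposite 3 interferon-stimulated genes were lower in the overexpression-labelled libraries when opposite-strand counts were summed by gene, a comparison chosen after seeing the data. The feature opposite MX1, an antiviral GTPase gene, fell by 0.76 on the log2 scale (SE 0.10), from 652 ± 46.4 CPM in controls to 386 ± 18.03 CPM (SD, n = 3). That opposite OAS1, which encodes an antiviral oligoadenylate synthetase, fell by 0.90 (SE 0.15), from 230 ± 16.5 to 123 ± 17.0 CPM. That opposite XAF1, a pro-apoptotic interferon-stimulated gene, fell by 1.51 (SE 0.24), from 135 ± 24.7 to 47.2 ± 15.6 CPM. The edgeR adjusted p were 0.0243, 0.0460 and 0.0460, among 3134 genes whose opposite-strand features held 64.8% of all counts. Each of these 3 sums held 1 feature, so the counts are those already tested above and are no further evidence. Among all 11851 genes the same counts had edgeR adjusted p of 0.184, 0.184 and 0.0778. The fits differ in the genes tested and in scaling. An unadjusted p below 0.05 was found for 175 of the 3134 genes, 101 higher and 74 lower. If no gene differed, a share of about 0.05 would fall below that limit. Some of their features are themselves protein-coding genes, so those reads cannot be assigned to the named gene alone. The lncRNA opposite MX1 (ENSG00000228318, chromosome 21, 41441056 to 41445708, minus strand) shares 236 exonic bases with it. That opposite OAS1 (ENSG00000257452, chromosome 12, 112907628 to 113017751, minus strand) shares 92 bases and extends beyond OAS1, which ends at 112933219. Each feature was assigned only to the protein-coding gene with the largest exonic overlap. The reads of this feature therefore cannot be assigned to OAS1 alone. PRAL (ENSG00000279296, chromosome 17, 6772831 to 6776116, minus strand) shares 2535 bases with XAF1. DESeq2 and limma-voom each called these 3. The calls depended on the libraries, with 0 features passing without control replicate 2, overexpression-labelled replicate 1 or overexpression-labelled replicate 3, 1 without overexpression-labelled replicate 2 and 69 without control replicate 3. With library totals in place of TMM 1 passed, and 0 passed with the own-strand ratio as a covariate, where the log2 fold changes were -0.73, -0.88 and -1.45 for MX1, OAS1 and XAF1 (SE 0.13, 0.18 and 0.26). Among contained features alone, a class without these 3, 0 passed.

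**Figure D3:**
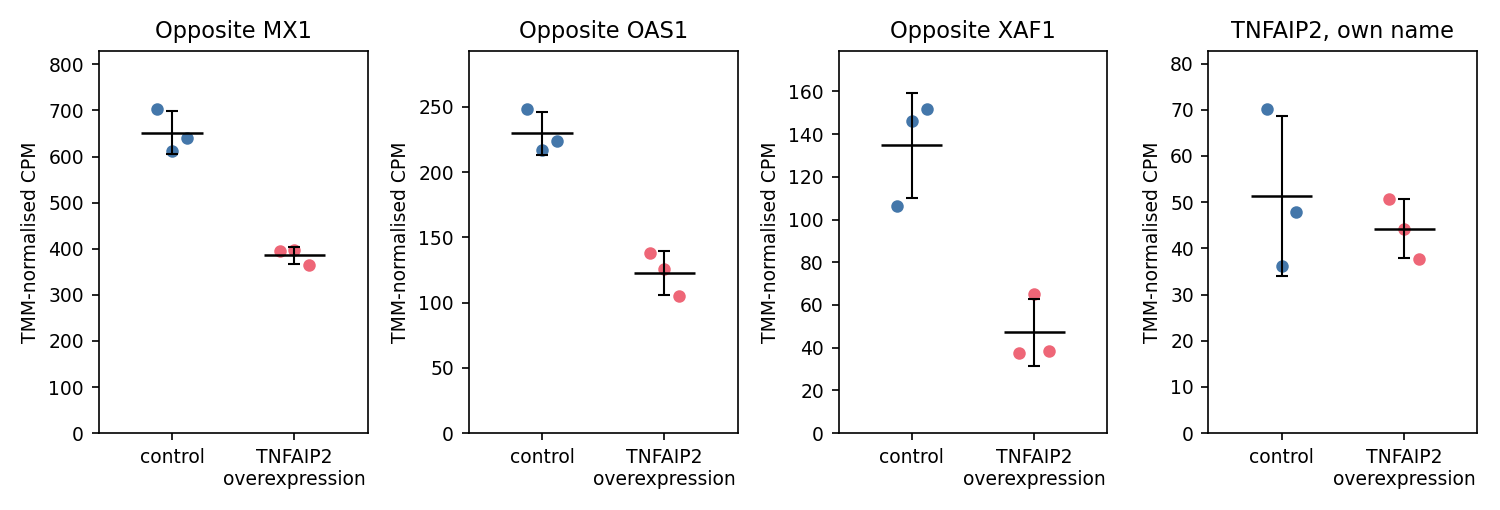
TMM-normalised CPM (vertical axes, from 0) is drawn for each library (points) of the control and TNFAIP2 overexpression groups, with the group mean (line) and SD (bars, n = 3). The features opposite MX1, OAS1 and XAF1 are lower in all 3 overexpression-labelled libraries than in any control, while TNFAIP2 under its own name overlaps between the groups.

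The other interferon-stimulated genes with an opposite-strand feature did not pass. Those with a positive log2 fold change were PARP9 at 0.62 (SE 0.30), IFIT2 at 0.31 (SE 0.38) and DTX3L at 0.19 (SE 0.24). Their features are themselves protein-coding genes (DTX3L, LIPA and PARP9), so these reads cannot be assigned to either strand's gene. Over all 7 interferon-stimulated genes read in this way, 3 of which were positive (median -0.16, mean -0.32), the camera adjusted p was 0.556, and 0 of 24 lists tested on opposite-strand features passed by camera (adjusted p up to 0.947) or by fry's directional form. By fry's mixed form, which tests for changes in either direction, 2 passed, the interferon-stimulated genes (adjusted p = 0.00380) and the G1/S and DNA replication genes (adjusted p = 0.0345, 2 of 12 positive). NF-κB targets read in this way had 5 of 5 positive log2 fold changes (median 0.059, mean 0.081), at 0.0041 (SE 0.14) for CFLAR, 0.06 (SE 0.19) for LIF, 0.14 (SE 0.25) for TNFAIP3 and 0.19 (SE 0.11) for IER3 (camera adjusted p = 0.639, SOD2 included, whose feature ACAT2 lies opposite a readthrough model of the locus). Opposite IER3, the antisense feature IER3-AS1 had 1294 ± 197 CPM in controls and 1480 ± 35.7 CPM in overexpression-labelled libraries. Of 6 metalloproteinase and plasminogen genes read in this way, 1 had a positive value (median -0.13, mean -0.011, camera adjusted p = 0.572) and none passed. Features opposite PLAU had 5328 ± 820 and 4768 ± 88.1 CPM, those opposite MMP1 71.2 ± 2.01 and 57.9 ± 4.87 CPM, and that opposite MMP11, the positive member, read on the protein-coding gene CHCHD10, 4.22 ± 1.12 and 8.06 ± 5.13 CPM.

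The 6 lists that camera placed higher under their own names did not pass on opposite-strand features. Each list had far fewer tested members there, and the own-name result was not computed on those members alone. This therefore does not show that the own-name shifts fail to hold. Ribosomal proteins had 3 of 8 positive log2 fold changes there, G2/M and mitosis genes 4 of 9, mesenchymal transition markers 3 of 5, oxidative phosphorylation genes 5 of 8, ribosome biogenesis genes 3 of 6 and proteasome subunits 3 of 8. The feature opposite PLK1 lay the other way, at 789 ± 136 CPM in controls and 666 ± 31.05 CPM in overexpression-labelled libraries (log2 fold change -0.24, SE 0.12, edgeR adjusted p = 0.786). Features opposite the mesenchymal marker TNC had 459 ± 55.8 and 451 ± 16.2 CPM, and those opposite SPARC 293 ± 38.5 and 292 ± 35.6 CPM.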

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

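The tests with the own-strand ratio as a covariate, on genes without an opposite-strand overlap, and every test of opposite-strand features were chosen after the data were seen. The count of genes past the threshold under their own names was 0 and became 3 with DESeq2, 1 with limma-voom and 3 without a filter, in each case among the features opposite MX1, OAS1 and XAF1 (at least 2-fold: 2, 1 and 2). Leaving out each library in turn it ran from 0 to 922, at least 2-fold from 0 to 425 and list members from 0 to 74, each highest without control replicate 3. The cause of these moves was not tested. The 6 lists became 2 with the covariate (1 higher, and the interferon-stimulated genes lower), 1 on genes without an overlap (the interferon-stimulated genes, lower), 0 with an estimated correlation and 0 by fry, and ran from 2 to 10 leaving out a library. They were 5 without a filter, where the mesenchymal markers lost their call (adjusted p = 0.185), and 5 with a prior count of 0.5, where the proteasome subunits did (0.0527). The 3 opposite-strand features became 2 at an overlap of at least 200 bases, which leaves out OAS1, 1 at a density ratio of at least 2, where the adjusted p of the features opposite OAS1 and XAF1 rose to 0.0504, 1 with library totals, 0 with contained features and 0 with the covariate, and ran from 0 to 69. The class of contained features does not hold these 3. Leaving out a library, their log2 fold changes ran from -0.80 to -0.70 (MX1), -1.0003 to -0.81 (OAS1) and -1.82 to -1.38 (XAF1), with adjusted p up to 0.675.

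TNFAIP2 ran from -0.39 to 0.074 leaving out a library, positive without control replicate 1. NFKBIA turned to 0.17 with library totals, 0.22 with the covariate and up to 0.14 leaving out a library (lowest -0.22). NFKB1 turned to -0.26 with the covariate and down to -0.10 leaving out a library (highest 0.24). Leaving out a library, IKBKB ran from 0.11 to 1.66, CHUK from 0.15 to 0.83, IKBKG from -0.50 to -0.22 and RELA from 0.0034 to 0.29, and IKBKB was 0.026 with the covariate. These 4 kept their signs under each alternative that gave a value (IKBKB had none at 5 CPM in 3 libraries). The median log2 fold change of all genes was 0.02 with TMM and 0.18 with library totals. Libraries with the same number correlated at -0.25, 0.15 and -0.05 after the group means were taken out. These values show no pairing, but so few libraries cannot exclude shared cultures or days. With the replicate block 0 genes, 5 lists (proteasome subunits at 0.0568) and 3 opposite-strand features passed. Of simulated 2-fold changes, 21% were recovered under own names (common dispersion 0.0974) and 68% in opposite-strand sums (0.0377), and what part of this depth sets was not tested.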

Other observations

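The tests of the strand pattern, of the ribosomal protein list alone, of list means by library and of other splits for genes under their own names were chosen after the results were seen, as was the fit of opposite-strand features itself. In that fit, features opposite the antigen presentation gene HLA-F had 464 ± 103 CPM in controls and 318 ± 32.1 CPM in overexpression-labelled libraries (log2 fold change -0.55, SE 0.15, edgeR adjusted p = 0.761). Those opposite the immunoproteasome gene PSMB8 had 893 ± 92.2 and 757 ± 10.3 CPM (adjusted p = 0.786), while that opposite PSMB9, read on 139 bases of PSMB8 itself, lay the other way at 45.1 ± 7.33 and 63.3 ± 6.96 CPM (adjusted p = 0.786). Over the 9 antigen presentation genes read in this way, 3 values were positive (camera adjusted p = 0.572). These genes were picked after their values were seen and none passed.

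Of 7 angiogenesis and lymphangiogenesis ligands read in this way, 1 had a positive log2 fold change (median -0.20, camera adjusted p = 0.572). The feature with the second highest mean count, ENSG00000230021 on chromosome 1 (586071 to 827796, minus strand), had 106582 counts, 3.15% of the total, and lay opposite no protein-coding exon. The microRNA feature ENSG00000278791 at 632325 to 632413 of that chromosome had 52507 counts.

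Counts lay on features opposite abundant genes. Counting without regard to strand would leave such features no denser than the genes they lie in, but 346 of 369 contained features held at least 5 times the reads per base of their gene, which argues against it. A strand setting opposite to that of the stranded kit is a candidate explanation, since 363 of the 369 held more reads per base than their gene. Counts under a gene's own name ranked with those of the feature inside it (Spearman's rho = 0.637 across 369 pairs, which are not independent replicates), so they may be a small share of each gene's reads that kept the other strand. Whether the setting or the kit's orientation differed from its label stays open, and no biological explanation was tested.

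Under their own names, camera with the preset correlation placed 6 lists higher in the overexpression-labelled libraries, and 0 passed with an estimated correlation. All 6 had a higher median in control replicate 3 than in control replicates 1 and 2, though for the ribosomal proteins by 0.028 against 0.032 for all genes; that library may differ in other ways too, so this does not show the own-strand share to be the source. With the own-strand ratio as a covariate, 1 of the 6 was past the camera threshold and higher, and 5 medians lay between 0.086 and 0.22 while that of the proteasome subunits was -0.046. In list means by library, the slope on the log2 own-strand ratio and the group term were 0.49 (SE 0.087) and -0.055 (SE 0.072) for proteasome subunits, 0.58 (SE 0.12) and 0.10 (SE 0.099) for mesenchymal markers, 0.26 (SE 0.025) and 0.087 (SE 0.021) for ribosome biogenesis, 0.38 (SE 0.16) and 0.19 (SE 0.13) for G2/M and 0.13 (SE 0.089) and 0.20 (SE 0.074) for oxidative phosphorylation, so the first 3 went with the ratio (adjusted p = 0.0325, 0.0327 and 0.0117), but 0 group terms passed (lowest adjusted p = 0.147) and, with ratio and group correlated (0.595), a group difference stays open for each. The ribosomal protein list had an adjusted p of 5.03e-05 with the covariate, against 3.85e-05 without it, and medians of 0.22 and 0.27. In list means by library, its slope on the log2 own-strand ratio was -0.039 (SE 0.12) and its group term 0.21 (SE 0.10). On genes without an opposite-strand overlap, however, its adjusted p by camera rose to 0.210 and it was no longer called. That test also changes the genes compared, so whether the own-strand share is its whole cause stays open. With an estimated correlation the p was 0.110 and 0.0992, so whether the list differs between the groups stays open too.

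Features opposite MX1, OAS1 and XAF1 were lower in the overexpression-labelled libraries, while over all 7 interferon-stimulated genes read in this way the camera adjusted p was 0.556 (unadjusted p = 0.208 with an estimated correlation). Scaling and the own-strand share both predicted a median near 0, but it was -0.85 with library totals and -0.88 with the covariate, where SE rose from 0.10, 0.15 and 0.24 to 0.13, 0.18 and 0.26 with 3 residual degrees of freedom in place of 4, and adjusted p were 0.0920, 0.269 and 0.0920. Library totals could not decide on scaling, since the TMM factors of these sums lay between 0.953 and 1.02 and could move the median little. The covariate value argues against the own-strand share as the whole cause, although all 3 calls ended with the covariate. Those of OAS1 and XAF1 also ended with library totals. A lower interferon response across its genes is a hypothesis: under their own names 21 of 28 members were lower with the covariate (camera adjusted p = 0.0282, p = 0.111 with an estimated correlation), and without it 22 of 28 were (camera adjusted p = 0.141), with OAS3 at -0.78 and -0.41, MX1 at -0.80 and -0.37, IFI6 at -0.17 and -0.31 and ISG15 at 0.28 and -0.14 with and without it. It cannot be told apart from a chance difference or a difference between cultures here, and since TNFAIP2 was not higher under its own name and had no opposite-strand feature to read, no link to it could be tested.

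The 6 libraries can be split into 3 against 3 in 10 ways, too few for a share under 0.05. Under their own names the real split gave 0 genes, 0 of them at least 2-fold, and the highest other 511 and 239, and with a real count of 0 it was fixed that 10 of 10 splits give at least as many. For lists, 2 splits, the real one included, gave at least the real 6 (highest other 15), and for opposite-strand features 2, the real one included, gave at least the real 3 (highest other 57). These highest values all came from the split of control replicates 1 and 2 and overexpression-labelled replicate 2, the libraries with the lowest own-strand ratios, from the rest. These counts point to a structure of the libraries other than the group labels, and whether the own-strand ratio is its source was not tested.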
